A study of Mus musculus with 10 samples.

How the data were processed

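DNA methylation was measured by methylated DNA immunoprecipitation followed by hybridisation to a microarray (MeDIP-chip) in 10 samples of left hemibrain from male C57BL/6j mice, an inbred laboratory strain. In this assay DNA fragments that carry 5-methylcytosine are pulled down with an antibody and compared with total DNA of the same sample. Per the labels, the immunoprecipitated DNA carried the dye Cy5 and the input DNA carried Cy3 on every array, with no dye swap, so a positive ratio means more methylated DNA than in the input at that probe, relative to the other probes of the array. A dye effect on single probes therefore remains in the ratios and cancels between diets only as far as it was the same on all arrays. The mice entered 1 of 3 diets at 3 weeks of age and stayed on it for 24 weeks. The diets differed in the ratio of n-3 to n-6 polyunsaturated fatty acids, which was 7:1 in the enriched diet (ERD, 4 arrays), 1:1 in the balanced diet (BLD, 3 arrays) and 1:6 in the standard diet (STD, 3 arrays). The sample titles carry a separate identifier for each array but do not state that it is an animal, so p-values measure the spread between these samples. All titles, those of ERD and BLD included, end in the word CONTROL, which therefore does not tell the diets apart.

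Each array is an Agilent 2-colour design of mouse CpG islands, which are stretches of DNA rich in CpG dinucleotides that often overlie promoters. It holds 94687 features, of which 88737 are not controls, and its probes are 45 to 60 nucleotides long. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes list Agilent Feature Extraction 9.0. The deposited processed intensity of each channel was already background-subtracted and scaled between the dyes by a linear factor with no lowess term, per the file headers. The deposited files also give the median pixel intensity of each spot and of its local background, flags for spots well above background, saturated spots and outlier spots, and a log10 ratio of Cy5 over Cy3. Other deposited columns, such as the flags and the probe positions, are codes and not measurements. The series value table holds the same log10 ratio as deposited in the scanner files, rounded, with a largest difference of 0.00498 on the log10 scale and with no further centring, so its direction is that of the scanner files. Its medians per array lay between -0.0177 and 0.000978 on the log10 scale. Probe positions are on the mouse build mm9, per the file headers, and all coordinates below are on that build. The files used here pair no probe with a gene name, and the gene table at hand is on another build, so positions were not converted and no gene is named. The rule for regions to be named was therefore applied without its clause on gene symbols, and the gene lists, marker lists and single genes fixed before the data were examined were not tested.

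The log2 ratio of processed Cy5 over processed Cy3 intensity was computed per probe. Spots flagged as outliers were left out and each array was centred on the median of its non-control probes, with no loess or quantile step. Saturated spots were kept. Regions were formed from probes of 1 chromosome whose starts lay at most 500 bp apart and kept where they held at least 3 probes. This gave 13835 regions with 85655 probes, a median of 5 probes per region and a median length of 644 bp. The value of a region on an array is the mean of its probes. Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 10 arrays with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second limma fit used the log2 of the n-3:n-6 ratio of the diet as a numeric term. The adjusted p-values of regions below come from these fits. Per pairwise comparison, the 10 regions with the lowest p that were higher and the 10 that were lower were named, among regions whose direction held in every fit without 1 array. For the trend, 5 in each direction and all regions past the threshold were named. Measures with 1 value per array were compared with exact two-sided permutation tests. These tests cannot go below 0.0286 for 4 arrays against 3, or below 0.1 for 3 against 3.

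Chromosomes were compared as sets of regions with camera in limma, with a preset correlation of 0.01, with an estimated correlation, and with fry. This comparison, the comparison of the highest and lowest 10% of regions by level, its repeat with regions ranked by BLD alone, the correction for probe length, the array position as a block, and the length correction together with scaling were added after the data were seen. The other alternatives were fixed before the data were examined. They were normexp background correction with an offset of 50, loess, quantile normalization, scaling of all arrays to one spread, the series value table, filters on probes well above background, the slide as a block, array weights, other region definitions, single probes and leaving out each array. Normexp used median spot signals because mean signals were not among the columns used here. The GC content of probes could not be computed without sequences, and probe length served as a stand-in. The arrays lie in pairs on 5 slides. ERD fills 2 slides, BLD 1, and STD 1, and the remaining slide holds 1 BLD and 1 STD array, so that only BLD and STD can be compared within a slide.

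The share of non-control probes well above background in both channels ranged from 76.4% to 94.7% per array, and the number of arrays limits the precision. The median half-width of the 95% interval of a region's difference was 0.26 on the log2 scale for ERD against STD, 0.28 for BLD against STD and 0.26 for ERD against BLD. The procedure was tested on simulated data for the 13835 regions with the spread of the real ones. The simulated noise was independent between regions and arrays, so the shares below do not cover differences shared by whole arrays or slides. In the simulated ERD against STD comparison, 52.2% of 67 regions that differed by 0.5 on the log2 scale and 98.5% of 67 that differed by 1 were recovered. For BLD against STD the shares were 35.8% and 94.0%, for ERD against BLD 35.8% and 95.5%, and for the trend, over the range of the diets, 34.3% and 95.5%. In the same order of comparisons, starting with ERD against STD, 7 of 174, 11 of 164, 9 of 162 and 2 of 155 calls were false. Each share comes from 1 random draw of regions. ERD against STD and ERD against BLD had the same numbers of arrays and the same median SE, 0.12. The gap between 52.2% and 35.8% is therefore not a difference in power. Figures were drawn with matplotlib 3.10.9.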

Results

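Methylation of CpG islands in the left hemibrain was compared between 3 diets that were designed with equal caloric content and that differ in their ratio of n-3 to n-6 polyunsaturated fatty acids. The question was whether the diet, given for 24 weeks from an age of 3 weeks, goes with a different methylation pattern in the brain. The enriched diet (ERD) had 4 arrays, and the balanced diet (BLD) and the standard diet (STD), which serves as the control, had 3 each. Every array measured 88737 probes. The share of probes well above background in both channels was 88.5% ± 5.1 (SD, n = 4) in ERD, 89.6% ± 1.4 (SD, n = 3) in BLD and 81.5% ± 6.8 (SD, n = 3) in STD. STD replicate 3 had the lowest share of all arrays, at 76.4%.

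The hemibrains had a shared pattern of log2 ratios across CpG islands, to which probe and dye effects common to all arrays can contribute. Of 13835 regions, 1144 lay above the array median on all 10 arrays and 2209 lay below it on all 10. Shorter clusters of probes had higher log2 ratios than longer ones, a difference read from the medians and not tested. Regions of 3 to 5 probes had a median log2 ratio of 0.0031, and 10.9% of these 7256 regions lay below the array median on all arrays. Among the 1225 regions of over 10 probes the median was -0.085, and 26.7% lay below the array median on all arrays. The highest mean level was that of 4 probes on chromosome 9 from 122075655 to 122076150, with 1.07 ± 0.46 (SD, n = 4) in ERD, 0.98 ± 0.15 (SD, n = 3) in BLD and 1.35 ± 0.49 (SD, n = 3) in STD. The lowest was that of 3 probes on chromosome 6 from 124779297 to 124779662, with -1.30 ± 0.29 (SD, n = 4), -0.81 ± 0.07 (SD, n = 3) and -0.73 ± 0.16 (SD, n = 3). Among the assembled chromosomes, the 385 regions of the X chromosome had the highest median level, at 0.05, followed by 0.00060 for the 1002 regions of chromosome 7, and chromosome 13 had the lowest, at -0.08. Over regions, which are not independent replicates, pairs of arrays correlated with a mean r of 0.703 within ERD, 0.736 within BLD and 0.436 within STD, and of 0.491 between ERD and STD.

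The spread of log2 ratios within an array had the highest mean in ERD and the lowest in STD. The spread follows how strongly the immunoprecipitation separated methylated from unmethylated probes, and it scales every difference. By itself it therefore cannot tell a change in methylation from a change in the strength of the pull-down. The interquartile range of log2 ratios was 0.71 ± 0.08 (SD, n = 4) in ERD, 0.61 ± 0.20 (SD, n = 3) in BLD and 0.47 ± 0.08 (SD, n = 3) in STD. The 4 ERD arrays lay above the 3 STD arrays, with an exact permutation p of 0.0286, which is the smallest this design allows and which became 0.0857 after adjustment over the 3 pairs of diets. BLD and STD differed by 0.14 (exact p = 0.3, adjusted 0.45), or by 0.07 without BLD replicate 1, 0.09 without BLD replicate 2 or without STD replicate 3, and 0.25 without BLD replicate 3, and ERD and BLD by 0.10 (exact p = 0.514, adjusted 0.514). On the slide that holds both diets the order was the other way, with 0.38 for BLD replicate 3 and 0.51 for STD replicate 1. Without BLD replicate 3 the difference between ERD and BLD turned to -0.017, so the order of these diets rests on that array. With normexp background correction the ERD and STD difference turned to -0.46. In the 10% of regions with the lowest level, ranked by the mean of the 3 diets and so in part by the arrays compared, the array medians were -0.45 ± 0.02 (SD, n = 4) in ERD, -0.37 ± 0.11 (SD, n = 3) in BLD and -0.28 ± 0.07 (SD, n = 3) in STD, with an exact p of 0.0286 between ERD and STD, or 0.0857 adjusted over the 3 pairs. In the 10% with the highest level they were 0.66 ± 0.37 (SD, n = 4), 0.58 ± 0.21 (SD, n = 3) and 0.27 ± 0.19 (SD, n = 3), with an exact p of 0.171 and an adjusted p of 0.3 between ERD and STD. There, ERD replicate 2 lay at 1.20 and the other ERD arrays at 0.39 to 0.62. With regions ranked by their level in BLD alone, the medians of the lowest 10% were -0.37 ± 0.03 (SD, n = 4) in ERD and -0.20 ± 0.07 (SD, n = 3) in STD (exact p = 0.0286, adjusted 0.0571 over both classes), and those of the highest 10% differed by 0.40 (exact p = 0.171, adjusted 0.171).

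**Figure D1:**
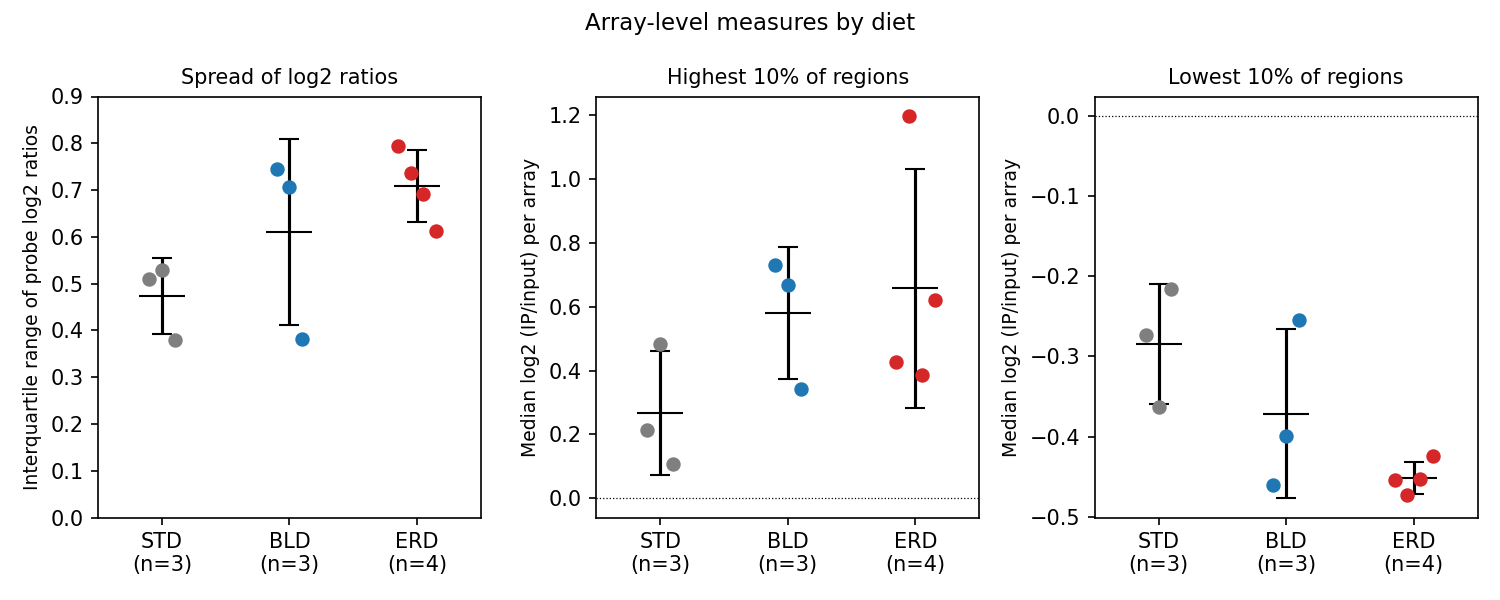
Each point is 1 array and bars give the mean ± SD of a diet; the panels show the interquartile range of probe log2 ratios and the median log2 ratio of the 10% of regions with the highest and the lowest level. The 4 ERD arrays lie above the 3 STD arrays in the first panel and below them in the last.

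The comparison of ERD with STD asks how a diet rich in n-3 fatty acids differs from the standard one. No single region passed the adjusted threshold, and the differences with the lowest p were toward less methylation signal in ERD. The 8 regions with an adjusted p under 0.1 were all lower in ERD. On chromosome 19 from 34266845 to 34267333, the log2 ratio of 4 probes was -0.69 ± 0.06 (SD, n = 4) in ERD and -0.02 ± 0.04 (SD, n = 3) in STD, a difference of -0.67 ± 0.09 (SE; limma adjusted p = 0.0602). On chromosome 3 from 96025351 to 96025559, 3 probes gave -0.87 ± 0.20 in ERD and 0.09 ± 0.21 in STD, a difference of -0.96 ± 0.13 (SE; adjusted p = 0.0602). On chromosome 9 from 123760507 to 123761334, 5 probes gave -0.60 ± 0.15 and 0.13 ± 0.10, a difference of -0.72 ± 0.10 (SE; adjusted p = 0.0602). A region of 4 probes on chromosome 14 from 27354098 to 27354556 was at -0.80 ± 0.04 in ERD, -0.69 ± 0.07 in BLD and -0.25 ± 0.03 in STD (ERD minus STD adjusted p = 0.0602). The remaining 6 named regions with lower values differed by -0.57 to -0.89, with adjusted p from 0.0602 to 0.137.

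The named regions with higher values in ERD had adjusted p from 0.137 to 0.156 and held 3 to 5 probes. The region with the lowest p lay on chromosome 18 from 36020156 to 36020488, where the log2 ratio was 0.72 ± 0.15 (SD, n = 4) in ERD, 0.47 ± 0.29 (SD, n = 3) in BLD and -0.04 ± 0.11 (SD, n = 3) in STD. The widest difference among them, 1.26 ± 0.24 (SE; limma adjusted p = 0.156), lay on chromosome 5 from 148673891 to 148674376. There, 4 probes gave 1.31 ± 0.50 in ERD and 0.05 ± 0.11 in STD, with 1 ERD array at 2.05 and the other 3 between 0.96 and 1.12. On chromosome 2 from 174122729 to 174123051, 3 probes gave 0.96 ± 0.38 in ERD, 0.43 ± 0.38 in BLD and -0.12 ± 0.07 in STD. BLD lay between ERD and STD in 19 of the 20 named regions, which were chosen for their distance between ERD and STD. In 3 of the 20, under 50% of spots were well above background in at least 1 diet.

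Over all regions, 0 of 13835 passed the adjusted threshold in limma, and 2173 (15.7%) had an unadjusted p under 0.05, 1063 of them higher and 1110 lower in ERD. The arrays of both diets did not overlap in 16.2% of regions, where chance gives 5.71%. The direction followed the level of the log2 ratio. Among the 1384 regions of highest level in BLD, a ranking that holds no ERD or STD array, 386 were higher in ERD at an unadjusted p under 0.05 and 0 were lower, while among the 1384 of lowest level in BLD 7 were higher and 330 were lower. Over regions, which are not independent, the difference between ERD and STD correlated with the level in BLD at r = 0.651. After all arrays were scaled to one spread, r was 0.36 and the slope on that level fell from 0.51 to 0.256. ERD and STD lie on separate slides, and with the slide as a random block 0 regions passed and 14.5% had a p under 0.05. Without STD replicate 3 the share was 8.62%, with normexp background correction it was 8.72%, and quantile normalization passed 10 regions, 5 higher and 5 lower. Normexp also turned the direction of 5 of the 20 named regions, among them that of chromosome 14.

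**Figure D2:**
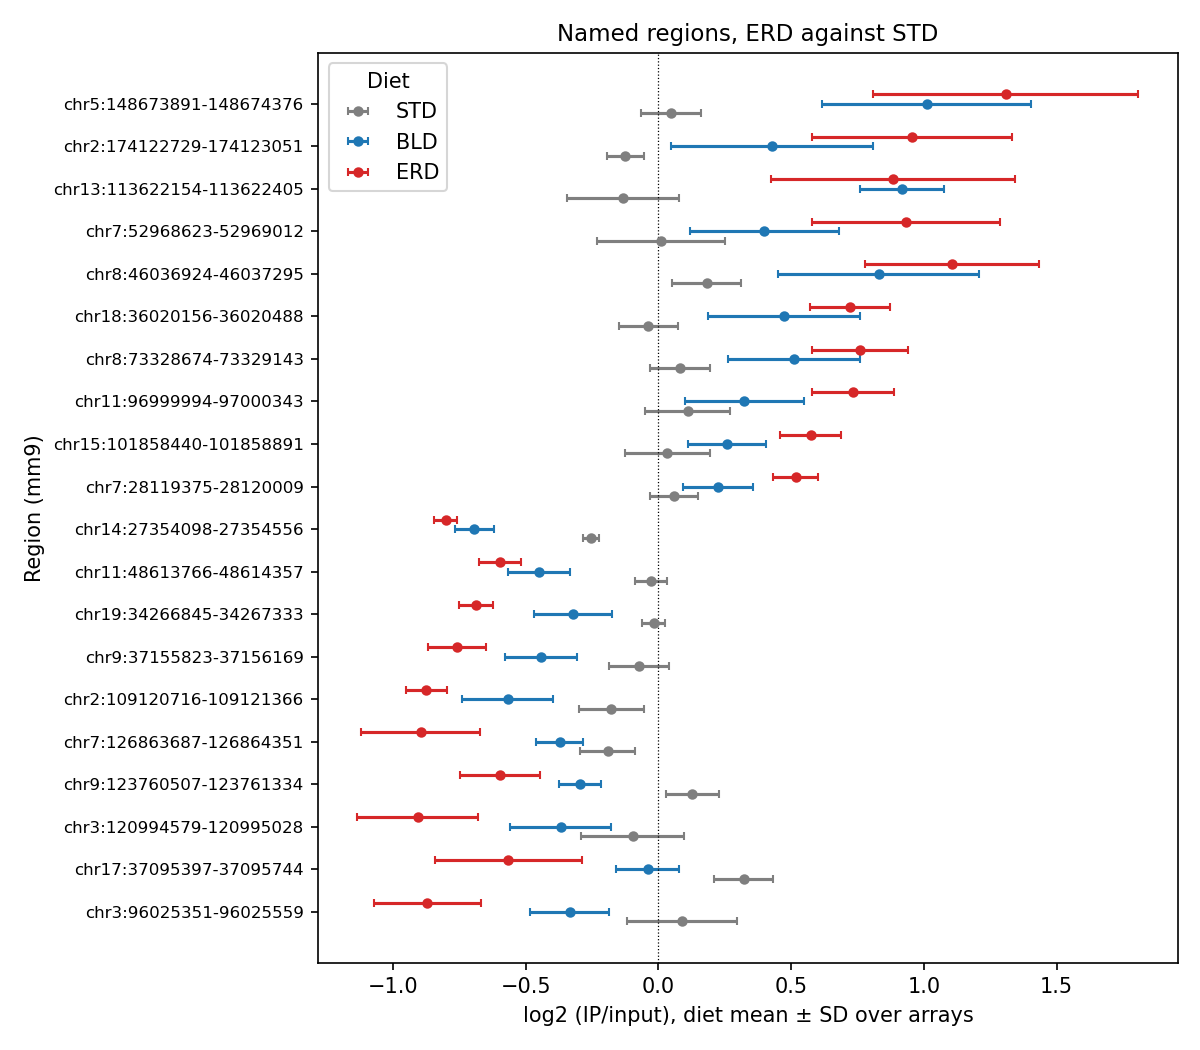
The 20 named regions of the ERD and STD comparison, with the mean log2 ratio of each diet on the horizontal axis and the SD over its arrays as bars (n = 4 for ERD, 3 for BLD and 3 for STD). BLD lies between the other diets in 19 of the 20, which were chosen for their distance between ERD and STD.

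The comparison of BLD with STD sets a ratio of 1:1 against the 1:6 of the standard diet. No region passed the adjusted threshold, and the named regions with higher values in BLD were wider in difference than those with lower values, at 0.47 to 1.05 against -0.42 to -0.63. The widest lay on chromosome 13 from 113622154 to 113622405, where 3 probes gave 0.92 ± 0.16 (SD, n = 3) in BLD, 0.88 ± 0.46 (SD, n = 4) in ERD and -0.13 ± 0.21 (SD, n = 3) in STD. Only 33.3% of the spots of this region were well above background in each diet. On chromosome 19 from 7315635 to 7315974, 3 probes gave 0.36 ± 0.11 in BLD against -0.29 ± 0.21 in STD and -0.33 ± 0.06 in ERD, so that BLD stood apart from both other diets. On chromosome 17 from 21082131 to 21082881, 6 probes gave -0.55 ± 0.03 in BLD and -0.08 ± 0.09 in STD. The region of chromosome 14 described above was lower by a similar amount in BLD, with a difference of -0.44 ± 0.09 (SE; limma adjusted p = 0.44). All 20 named regions had this adjusted p. In limma 0 of 13835 regions passed, and 1549 (11.2%) had an unadjusted p under 0.05, of which 1011 were higher and 538 lower in BLD. Over all regions the median difference was 0.03 and 56.7% were higher in BLD. Since each array was centred on its own median, this does not measure a difference in total methylation. The arrays of both diets did not overlap in 17.4% of regions, where chance gives 10%. Among the 10 splits of these 6 arrays, another split gave a higher share at an unadjusted p under 0.05, at 13.4%.

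The 20 named regions had the same direction in the pair of arrays that share a slide, and that pair is part of the fit that chose them. There the difference was 1.25 for the region of chromosome 13, 0.44 for that of chromosome 19 and -0.43 for that of chromosome 14. With the slide as a fixed block, the difference between BLD and STD is that of this 1 pair of arrays alone. That fit therefore cannot show whether the slide accounts for the differences. In the fit of the 2 diets alone 2 regions passed. The share at an unadjusted p under 0.05 was 4.44% without BLD replicate 1, 5.43% without BLD replicate 2 and 18.7% without BLD replicate 3. It was 18.7% with array weights and 3.59% with normexp background correction. Normexp turned the direction of 12 of the 20 named regions, among them those of chromosomes 13, 14 and 19 given here.

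The comparison of ERD with BLD separates the enriched from the balanced diet. Again no region passed the adjusted threshold, and regions at an unadjusted p under 0.05 were more often lower than higher in ERD, at 929 against 481 of 13835. They made up 10.2% of regions. The median difference over all regions was -0.03, and 43.6% of regions were higher in ERD. Since each array was centred on its own median, neither value measures a difference in total methylation. The region of chromosome 19 from 7315635 to 7315974 headed the lower side, with a difference of -0.69 ± 0.11 (SE; limma adjusted p = 0.422). A region of 3 probes on chromosome 8 from 87364036 to 87364692 was at -0.21 ± 0.23 (SD, n = 4) in ERD, 0.49 ± 0.15 (SD, n = 3) in BLD and -0.15 ± 0.03 (SD, n = 3) in STD. In both of these regions, only 33.3% of the STD spots were well above background. On the higher side, 5 probes on chromosome 5 from 104084379 to 104084829 gave 0.00 ± 0.07 in ERD and -0.51 ± 0.20 in BLD. On chromosome 4 from 140581070 to 140581513, 3 probes gave 0.79 ± 0.12 in ERD, 0.20 ± 0.03 in BLD and 0.32 ± 0.27 in STD. All 20 named regions had an adjusted p of 0.422. The arrays of both diets did not overlap in 10.1% of regions, where chance gives 5.71%. Of the 35 splits of these 7 arrays, 5 gave as large a share at an unadjusted p under 0.05, with 15.3% as the highest. No slide holds arrays of both diets, and with the slide as a random block 0 regions passed and 9.48% had an unadjusted p under 0.05. With normexp background correction that share was 0.484%. It was 6.52% without BLD replicate 1 and 6.74% without BLD replicate 2, in the fits with no block. Scaling all arrays to one spread gave 6.32% and array weights gave 15%.

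The trend over the diets asks which regions follow the n-3:n-6 ratio from 1:6 over 1:1 to 7:1. Methylation signal fell with a rising share of n-3 fatty acids in 6 of 13835 regions and rose in 0, while quantile normalization gave 10 regions, 6 rising and 4 falling. The steepest slope was that of the 3 probes on chromosome 3 from 96025351 to 96025559, which fell by 0.18 ± 0.02 (SE; limma adjusted p = 0.0394) on the log2 scale per doubling of the ratio, with diet means of 0.09 in STD, -0.33 in BLD and -0.87 in ERD. The slope was -0.17 ± 0.03 on chromosome 17 from 37095397 to 37095744 (adjusted p = 0.0446), where the diet means were 0.32, -0.04 and -0.57. In that region only 33.3% of spots in STD, 41.7% in BLD and 31.25% in ERD were well above background in both channels. The region of chromosome 19 from 34266845 to 34267333 fell by 0.12 ± 0.02 (adjusted p = 0.0394), and that of chromosome 9 from 123760507 to 123761334 by 0.13 ± 0.02 (adjusted p = 0.0439). The other 2 regions lay on chromosome 9 from 37155823 to 37156169 and on chromosome 2 from 109120716 to 109121366, with slopes of -0.13 each (adjusted p = 0.0439). All 6 are among the regions with lower values named for ERD and STD. The 5 named regions with rising values had slopes of 0.10 to 0.20 and an adjusted p of 0.115.

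At an unadjusted p under 0.05, 2079 regions (15%) followed the ratio, 981 rising and 1098 falling. The 6 calls were lost with the slide as a random block (slopes of -0.18 to -0.12, limma adjusted p = 0.0827) and with loess (slopes of -0.17 to -0.12, adjusted p from 0.083 to 0.0973), while the slopes stayed close to their first values. With normexp background correction the slopes shrank to between -0.06 and -0.01 (adjusted p from 0.488 to 0.685). The calls depended on single arrays, while the 6 slopes stayed between -0.192 and -0.115 in all fits without 1 array. Leaving out BLD replicate 1 kept 5 of the 6 and leaving out ERD replicate 4 kept 1, while leaving out any of the other 8 arrays left 0 regions past the threshold. Of the spots in the 6 regions, 66.3% were well above background in both channels, against 86.7% over all regions, and no region of the 6 held 3 probes that were so on every array. The region of chromosome 17 held 0 such probes among its 4. Restricted to such probes, the trend passed in 2 other regions, 1 rising and 1 falling. The rising one was the region of chromosome 18 from 36020156 to 36020488, with a slope of 0.15 and a limma adjusted p of 0.0267.

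**Figure D3:**
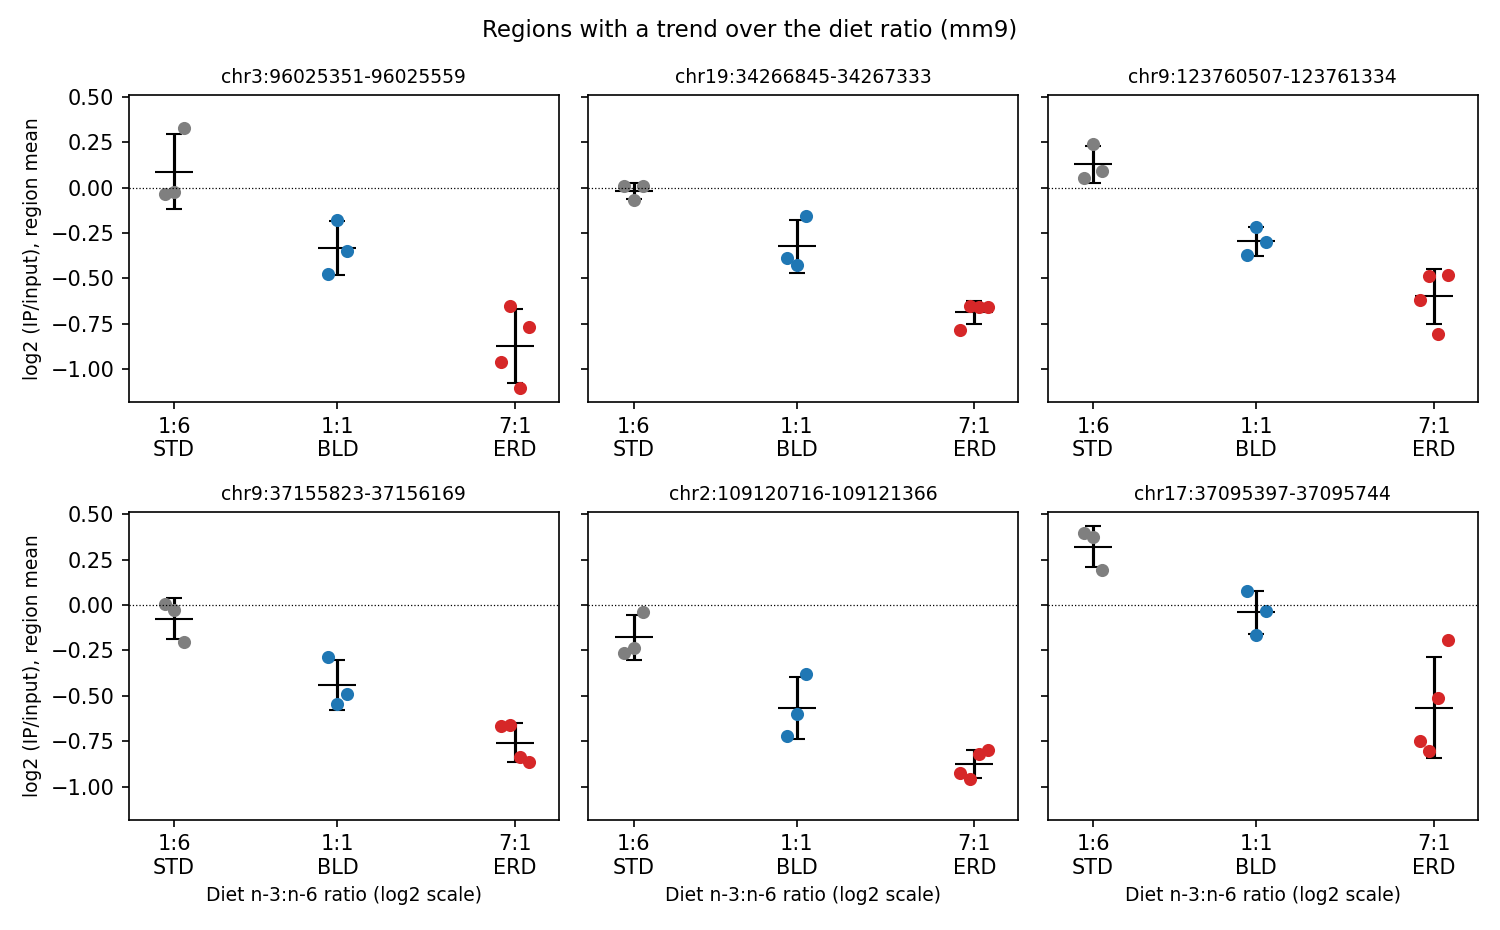
The 6 regions with a trend, with the n-3:n-6 ratio of the diet on a log2 axis and the log2 ratio of immunoprecipitated over input DNA on the vertical axis; points are arrays and bars the mean ± SD of a diet. In each region the mean falls from STD over BLD to ERD.

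By chromosome, X-linked islands had the highest median difference in all 3 comparisons. Between BLD and STD it was 0.056, close to the 0.051 of chromosome 15. The median difference between ERD and STD was 0.10 over the 385 regions of the X chromosome, and the next highest median was 0.03 on chromosome 15. With camera at a preset correlation of 0.01, the X chromosome was the only one of 20 that passed, higher in ERD than in STD (adjusted p = 0.000199) and than in BLD (adjusted p = 0.00115, median difference 0.03), and 0 passed between BLD and STD. Both calls were lost with an estimated correlation (adjusted p = 0.986 and adjusted p = 0.993). With fry, 0 chromosomes passed in all 3 comparisons. The medians of X-linked regions per array were 0.10 ± 0.05 (SD, n = 4) in ERD, 0.05 ± 0.05 (SD, n = 3) in BLD and 0.01 ± 0.05 (SD, n = 3) in STD, with an exact p of 0.0857 between ERD and STD and an adjusted p of 0.257 over the 3 pairs. The call against BLD was lost without BLD replicate 3, and both calls were lost with normexp and with single probes. The X-linked minus autosomal median, 0.10 for ERD and STD and 0.06 for ERD and BLD, was -0.00022 and 0.011 with normexp but 0.085 and 0.077 with single probes. It was 0.065 and 0.047 with all arrays scaled to one spread, and 0.11 and 0.10 with loess.

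**Figure D4:**
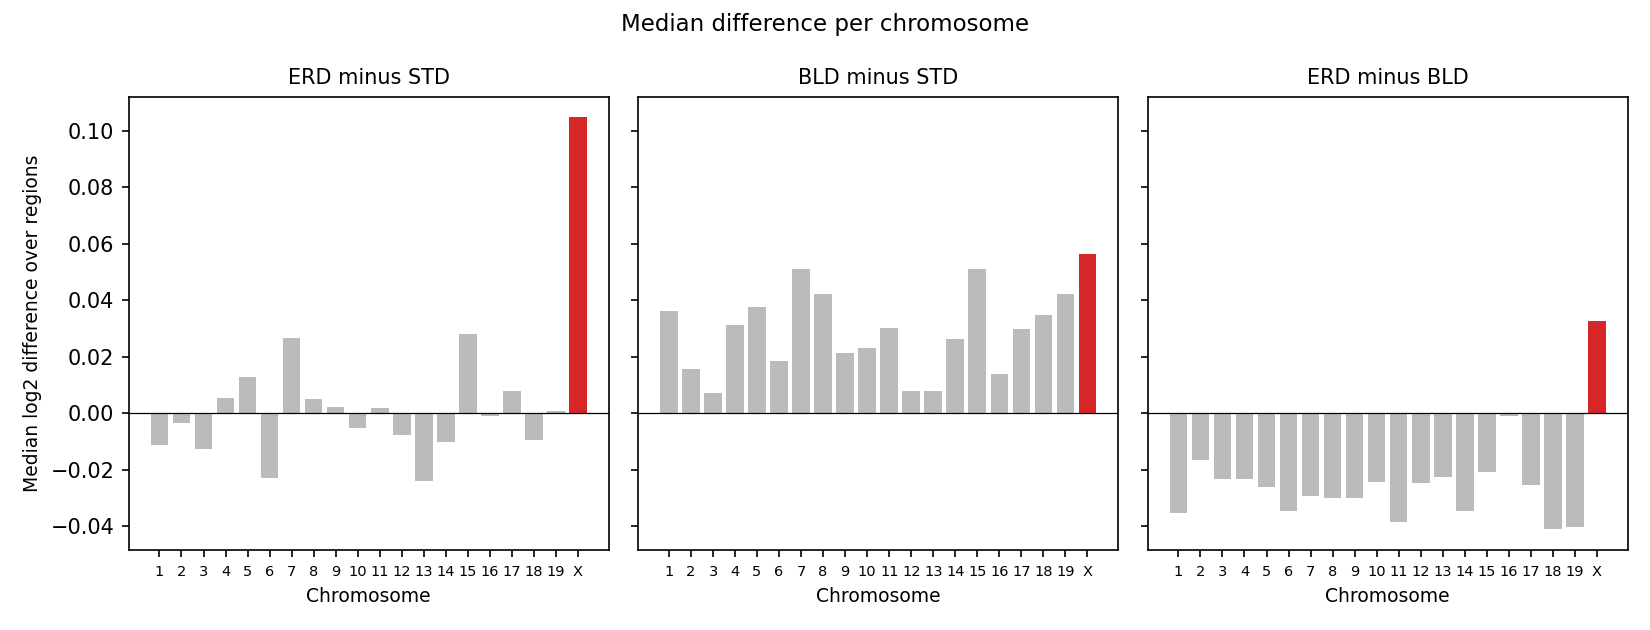
Median log2 difference over the regions of each chromosome for the 3 comparisons of diets, with the X chromosome in red. In the comparison of ERD with STD the X chromosome lies at 0.10 and the next highest, chromosome 15, at 0.03.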

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

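Among 72 sets of 4 ERD arrays, made of the measures per array and the named regions, 5 held 1 array far from the other 3 by Dixon's ratio, and chance gives about 1 in 20. The median log2 ratio of probes of 45 nucleotides was -0.039 on 1 ERD array and -0.074 to -0.070 on the other 3. On chromosome 5 from 148673891 to 148674376, 1 ERD array gave 2.05 and the other 3 gave 0.96 to 1.12. On chromosome 8 from 73328674 to 73329143, the values were 1.03 against 0.65 to 0.70. On chromosome 19 from 34266845 to 34267333, they were -0.78 against -0.66 to -0.65. On chromosome 8 from 87604137 to 87604561, they were -0.447 against -0.462 to -0.460. Of the tests reported in this part, those on a common spread for the first pattern, on probes near background for the second, on the most shifted of any chromosome for the third, and on other splits for the shares of regions in the comparisons with BLD were chosen after the result was seen.

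The first pattern is the share of 15.7% of regions at an unadjusted p under 0.05 between ERD and STD, with the direction following the level. Of the 35 splits of these 7 arrays, 1 gave a share as large, the real one, and the highest other was 12.7%. That meets the bound of 0.05 set beforehand, but it is the smallest share the design allows and is not adjusted for the 3 comparisons. Chance is therefore argued against but not excluded, and the real split also parts the slides. The share was 13.6% after scaling all arrays to one spread (9.16% to 18.3% on leaving out single arrays), 16.3% after correction for a probe length trend (9.08% to 17.1%) and 17.8% on probes well above background (9.16% to 18.6%). Each range reaches below the bound of 10% set for excluding an explanation, as did the uncorrected share without STD replicate 3 (8.62%), so by that bound none of these 3 is excluded. The length correction did not lower the share, which argues against a probe length trend as the source of all of it. The brighter probes did not lower it either. Normexp background correction did, to 8.72%, but it changes the signal of all probes and so does not single out those near background. Probes near background stay open by the bound given above. A difference in spread stays open too. Diet and slide cannot be told apart here, since no slide holds arrays of both diets, and an effect of diet stays open and untested.

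The second pattern is the 6 regions whose signal fell with the n-3:n-6 ratio. Of 100 assignments of the arrays to the diets, 1 gave as many, the real one, and the highest other gave 0. This argues against chance but does not exclude it. The assignments did not keep the arrays of a slide together, and all calls were lost on leaving out most of the single arrays. A probe length trend as the cause is argued against by a median slope of 6.92 times its SE after correction. Scaling to one spread left a median of 5.76 times the SE (3.76 to 7.75) and 1 region past the threshold, with the median slope moving from -0.13 to -0.11 and its SE from 0.019 to 0.021, so a difference in spread stays open. The 5 lost regions had a smaller slope relative to its SE than before, and for that of chromosome 19, at 6.9 against 7.35, the adjusted p rose from 0.0394 to 0.0622 as its unadjusted p rose from 5.7e-06 to 9e-06, at rank 2 in both fits. Probes near background remain a candidate source, since the share of spots well above background in both channels lay at the 0.02 percentile of 10000 random sets of 6 regions, and that in the input channel alone at the 0.55 percentile, and an effect of diet or slide stays open.

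The third pattern is the X-linked shift between ERD and STD. The X-linked median lay 0.104 above the autosomal one, as far as in 1 of 35 splits, the real one, with 0.103 as the highest other, and the most shifted of any chromosome was as far from the rest in 1 of 35 splits too. That margin is narrow, the X-linked medians per array gave an exact p of 0.0857, and a chromosome past the threshold appeared in 9 of the 35 splits, with 1 as the highest other count, so chance is not excluded for the X-linked shift. Against 20 autosomal regions matched on level and probe length, the X-linked excess was 0.039 (95% bootstrap interval over regions 0.028 to 0.053). This lay between the bounds set for and against a difference in spread and level. The level was the mean over all arrays, ERD and STD included, so the matching itself can lower the excess. The interval does not cover the spread between arrays. A difference in spread and level therefore stays open. An effect of diet stays open and untested.

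Counts past the threshold were set against other splits of the arrays. For ERD and STD the real count of regions was 0 and 35 of 35 splits gave as many, with 178 as the highest other, from ERD replicates 1 and 3 with STD replicates 1 and 3 against the rest, while all the remaining splits gave 0. A count so far above the real one points to a structure of the samples. The arrays set against the rest had the lowest medians of the highest 10% of regions, at 0.11 to 0.43 against 0.48 to 1.20. Whether this accounts for the count was not tested. For ERD and BLD the real count was 0, as many in 35 of 35 splits, with 33 as the highest other, from ERD replicates 1, 3 and 4 with BLD replicate 3. Those arrays too had the lowest such medians, at 0.34 to 0.62 against 0.67 to 1.20 in the rest. Neither split follows the slides. Chance cannot be excluded for the X chromosome between ERD and BLD either, since 9 of 35 splits gave 1 chromosome, which was also the highest other. The X-linked median lay 0.060 from the autosomal one in the real split and up to 0.082 in other splits. For BLD and STD the 10 splits are too few for a share under 0.05. There the real counts were 0 regions and 0 chromosomes, which 10 of 10 splits matched, and the highest others were 0 and 1. The share of regions at an unadjusted p under 0.05 was 11.2% there, as large in 2 of the 10 splits, with 13.4% as the highest other. For ERD and BLD that share was 10.2%, as large in 5 of 35 splits with 15.3% as the highest other, so chance cannot be excluded for it.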

How the results depend on the processing

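The correction for probe length, the block for array position, the length correction with scaling, the ranking of regions by BLD alone, and the chromosome comparison were chosen after the data were seen. Between ERD and STD, the count of regions was 10 with quantile normalization (5 higher, 5 lower), 8 with array weights, 3 with the series value table and 1 with the median of probes, and 0 to 1 on leaving out single arrays, with 1 without ERD replicate 4. Between BLD and STD it was 2 in the fit of the 2 diets alone, and 0 to 2 on leaving out arrays, with 2 without ERD replicate 2 and 1 without BLD replicate 3. Between ERD and BLD it was 0 in all settings run. The trend count of 6, all falling, was 7 after length correction, 5 with array weights, and 4 with the series value table and with a gap of 1000 bp, again all falling. It became 10 with quantile normalization (6 rising, 4 falling), 2 with each filter on probes well above background, 1 with scaling to one spread, with the median of probes and with array position as a block, and 0 with normexp, loess, the slide as a random block, a gap of 200 bp, regions of any size, single probes, and length correction with scaling. It was 0 to 5 on leaving out arrays. The X chromosome call between ERD and STD became 0 with normexp, single probes, the length correction with scaling, the estimated correlation and fry. Between ERD and BLD it became 0 with normexp, single probes, the estimated correlation and fry, and ranged from 0 to 1 on leaving out arrays. The difference in interquartile range between ERD and STD turned to -0.458 with normexp, and its exact p, 0.0286 before and 0.0857 after adjustment over the 3 pairs, was 0.0571 unadjusted with the standard deviation (0.145) and after length correction (0.227). It ranged from 0.188 to 0.267 on leaving out arrays. Between BLD and STD it turned to -0.622 with normexp and ranged from 0.071 to 0.252 on leaving out arrays, and between ERD and BLD it ranged from -0.017, without BLD replicate 3, to 0.164. The cause was not tested for any of these. With normexp the share of regions at an unadjusted p under 0.05 was 8.72% for ERD and STD, 3.59% for BLD and STD and 0.484% for ERD and BLD. In the settings that measured them, other than leaving out arrays, where the rule for naming regions fixed the direction, named regions kept their direction except with normexp, which turned 5 of 20 for ERD and STD, 12 of 20 for BLD and STD, 1 of 20 for ERD and BLD, and 1 of 11 for the trend. For ERD and STD its values were -0.018 (chromosome 8 from 73328674), -0.25 (13 from 113622154), -0.066 (8 from 46036924), 0.158 (14 from 27354098) and 0.023 (7 from 126863687), and the X-linked minus autosomal median was -0.00022. For BLD and STD they were -0.227 and -0.22 (19 from 7315635 and 8810214), -0.167 (7 from 109044614), -0.183 (8 from 87364036), -0.338 (12 from 107173647), -0.221 (13 from 113622154), -0.046 (4 from 24824998), -0.045 (8 from 122923408), 0.161 (14 from 27354098), 0.078 (5 from 123526309), 0.032 (14 from 8835214) and 0.016 (8 from 41719873). For ERD and BLD the value was 0.012 (7 from 25756998), and for the trend -0.0023 (8 from 73328674). No paired analysis was possible because replicate numbers follow only the order of the arrays and pair no samples. Not run were the correction for GC content, genes as the unit, and the gene lists, which need sequences or gene names. Signal over background limits the dim probes: 51889 of 88737 were well above background in both channels on every array.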

Other observations

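Of the 20 regions named for BLD and STD, 4 were also among those named for ERD and STD, where ERD and BLD differed from STD in the same direction. Another 2 were also among those named for ERD and BLD, the one on chromosome 19 from 7315635 to 7315974 and the one on chromosome 8 from 87364036 to 87364692. Each pair of comparisons shares the arrays of 1 diet, so part of these overlaps needs no effect. Some islands of low ratio varied little over the arrays. The 5 probes on chromosome 14 from 27457424 to 27458155 had a mean log2 ratio of -0.71 with an SD of 0.07 over the 10 arrays and values from -0.80 to -0.56.

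Probes without a position in the files, 326 in number, had medians of 0.14 to 0.40 on the ERD arrays, 0.06 to 0.14 on the BLD arrays and -0.02 to 0.20 on the STD arrays. The 90 probes on unplaced contigs had medians of 0.11 to 0.35, 0.12 to 0.50 and 0.03 to 0.26. The difference in median log2 ratio between probes of 56 to 60 and of 45 nucleotides was 0.34 ± 0.09 (SD, n = 4) in ERD, 0.61 ± 0.38 (SD, n = 3) in BLD and 0.03 ± 0.12 (SD, n = 3) in STD, with an exact p of 0.0286 between ERD and STD and an adjusted p of 0.0857 over the 3 pairs. The 6 regions with a trend had a mean log2 input signal of 8.98, against 9.82 over all regions, which placed them at the 0.41 percentile of random sets of 6 regions.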
